A study of Mus musculus with 6 samples.

How the data were processed

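Gene expression was measured on 6 arrays, 3 of wildtype and 3 of Bach2 knockout CD4 single-positive thymocytes of the mouse, the thymic T cells that have kept the co-receptor CD4 and lost CD8. Per the labels' protocols, irradiated male Rag1 knockout recipients, which make no T or B cells of their own, received equal parts of Ly5.1-negative knockout and Ly5.1-positive wildtype bone marrow. Donors and recipients were 8 weeks old. The thymocytes of either genotype were sorted by flow cytometry from these mixed chimeras 2 months later, told apart by Ly5.1, an allele of the surface protein CD45 that is encoded by Ptprc. The design text says that the samples came from separate mice and that the 3 of each genotype were biological replicates. Total RNA was amplified, and 5.5 µg of single-stranded cDNA was fragmented and labelled with biotin, per the labels' protocols.

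The deposited values are on a log2 scale, 1 value per probe set and array, and the submitters' processing notes name RMA (robust multi-array average) and Partek, without versions. The scale is not stated and was read from the values, which ran from 1.10 to 13.2, were not centred per gene and had array medians of 4.93, 4.94, 4.97, 4.95, 4.93 and 4.94 for wildtype replicates 1 to 3 and knockout replicates 1 to 3. The genome build and further steps are not given in the sources used here. RMA sets every array to a common distribution, so a shift of all genes together would not be seen. Arrays give no read depth; their number, 3 per group, limits the precision.

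Gene symbols came from the platform's annotation, which can be old. Of 35556 probe sets, 21789 had 1 symbol, 1621 had several and 12146 had none listed, which leaves them unnamed here. Of those with 1 symbol, 21698 matched a RefSeq gene table of assembly GRCm38.p6 by gene number, and 0 symbols needed updating. That table served only for names and for which genes neighbour each other, and no coordinates are given. Probe sets with 1 symbol were tested, and each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. Probe sets of close paralogs (Abcb1a and Abcb1b, Ctla2a and Ctla2b) may bind labelled cDNA of either gene, so their separate values are uncertain.

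Knockout minus wildtype differences were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on adjusted p. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists that had at least 5 measured members, of 25 lists fixed. The lists held 358 distinct genes, of which 33 had no probe set under a single symbol here and were not tested. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Bach2, Ptprc, the 12 largest changes in each direction among genes whose 3 knockout values all lie on one side of the 3 wildtype values, and from each list up to 4 changed members with the largest differences. Where a list had no changed member, the 2 members with the smallest p are given as values only. Predicted genes, clone names, small RNAs and receptor segments, 7 of the changed genes, were counted and not named among the largest.

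The procedure was tested on simulated data with the 19938 genes and 6 arrays of the knockout and wildtype comparison. It recovered 31.8% of the genes changed by 0.5 on the log2 scale, 86.2% of those changed by 1 and 98.5% of those changed by 2, with 4 unchanged genes called and 0 sign errors. The simulated noise was normal, independent between genes and equally wide in both genotypes. The real wildtype arrays varied more than the knockout arrays, so recovery in the real data may differ. Alternatives were other empirical Bayes priors, no moderation, a filter on dim genes (mean of at most 4.93, which left 10658 genes), median centring, a second quantile normalization, array weights, averaged probe sets, all 35556 probe sets, a fold minimum of 2, the replicate number as a block, other list tests and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.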

Results

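RNA from sorted CD4 single-positive thymocytes was compared between Bach2 knockout and wildtype cells, with 3 arrays of each genotype and 19938 genes tested. Because both genotypes had matured in mixed chimeras, the comparison asked which transcripts differ with the genotype of the thymocytes themselves. It cannot tell a change within cells from a change in the mix of cells sorted. The Ly5.1 allele also went together with genotype. Bach2 encodes a transcriptional repressor of the basic leucine zipper family. Arrays correlated at 0.981 to 0.988 within wildtype, at 0.990 to 0.991 within knockout and at 0.984 to 0.989 between the genotypes. These are Pearson's r across all 35556 probe sets, which are not independent replicates. Wildtype arrays resembled knockout arrays about as much as each other. The lowest value was between wildtype replicates 1 and 2.

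Bach2 itself (probe set 10503695) was at 7.89, 8.20 and 8.05 on the log2 scale in the wildtype arrays and at 6.50, 6.42 and 6.52 in the knockout arrays. Its mean was 8.05 ± 0.16 in wildtype and 6.48 ± 0.06 in knockout cells (SD, n = 3 each), 2.96-fold lower in the knockout (limma, adjusted p = 0.000156). Which part of the gene was deleted is not given in the sources used here, so the remaining signal says nothing of remaining protein. Ptprc, whose allele marked the genotypes in the sort, was at 10.95 ± 0.07 and 10.98 ± 0.04, a difference of 0.03 that did not pass the test (adjusted p = 0.998).

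Of the genes tested, 70 were higher and 43 lower in knockout thymocytes. The 113 changed genes differed by 1.43-fold to 7.68-fold, with a median of 1.81-fold, and 23 of the higher and 18 of the lower genes differed at least 2-fold. The median difference over all genes was -0.01. At an unadjusted p under 0.05 there were 1377 genes, where chance would give 997. The 3 knockout and 3 wildtype values did not overlap for 2331 genes, 11.7% against the 10% that chance gives, and among these were all 113 changed genes.

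The largest rise was in Plac8 (probe set 10531724), from 5.57 ± 0.66 in wildtype to 8.51 ± 0.07 in knockout cells (SD, n = 3 each), a 7.68-fold difference (adjusted p = 0.000645). Atxn1 rose by 2.01 ± 0.23 on the log2 scale (limma standard error, as for the differences that follow; adjusted p = 0.00404). Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, rose by 1.88 ± 0.14 (adjusted p = 0.000208), and Prag1 rose by 1.67 ± 0.14 (adjusted p = 0.000465). Ccr4, a receptor for the chemokines Ccl17 and Ccl22, rose from 9.06 ± 0.10 to 10.71 ± 0.09 (SD, n = 3 each), and Il10ra, the ligand-binding chain of the receptor for interleukin 10, rose by 1.56 ± 0.13. The drug efflux transporters Abcb1a and Abcb1b rose by 1.54 and 1.31, though probes of these paralogs may not tell them apart. The long non-coding RNA Mirt1 (1.57), Ctla2a (1.36) and Rflnb (1.32) were also among the 12 largest rises. So was Lyz2, the lysozyme of myeloid cells, at 1.39 ± 0.23 (adjusted p = 0.0256). Its call was lost in 4 of 6 fits that left out an array, up to adjusted p = 0.153 without wildtype replicate 3.

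The largest fall was in Foxp3 (probe set 10598292), the lineage-defining transcription factor of regulatory T cells. It was at 7.98 ± 0.59 in wildtype and 5.54 ± 0.17 in knockout cells (SD, n = 3 each), 5.39-fold lower (adjusted p = 0.00148). Its wildtype values were 7.30, 8.29 and 8.33, all above the knockout values of 5.58, 5.36 and 5.69. The aspartic protease Ctse fell by 2.37 ± 0.12 (adjusted p = 5.16e-05), Arhgap20 fell by 2.11 ± 0.12, and Cd55, a surface inhibitor of complement, fell by 2.07 ± 0.15. Ctse and Cd55 are among the 300 tested genes nearest to Ptprc in gene order. The chemokine receptor Cxcr3 fell by 1.42 ± 0.16 (adjusted p = 0.00371). Il2ra, the alpha chain of the interleukin 2 receptor, fell by 1.93, Dapl1 fell by 1.92, Lrrc32, which holds latent TGF-beta at the cell surface, fell by 1.86. The decoy interleukin 1 receptor Il1r2 fell by 1.57, Ikzf2 (Helios) fell by 1.51 and the phosphatase Dusp4 fell by 1.36. These last 6 calls were not stable. Without wildtype replicate 3 the adjusted p was 0.133 for Il2ra, 0.0657 for Lrrc32, 0.164 for Il1r2, 0.0617 for Ikzf2 and 0.16 for Dusp4, and without knockout replicate 2 it was 0.0547 for Dapl1. Lrrc32 was lost without knockout replicate 2 as well, Il2ra and Il1r2 passed only without wildtype replicate 1, and Dusp4 passed only without wildtype replicate 1 or knockout replicate 3.

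**Figure D1:**
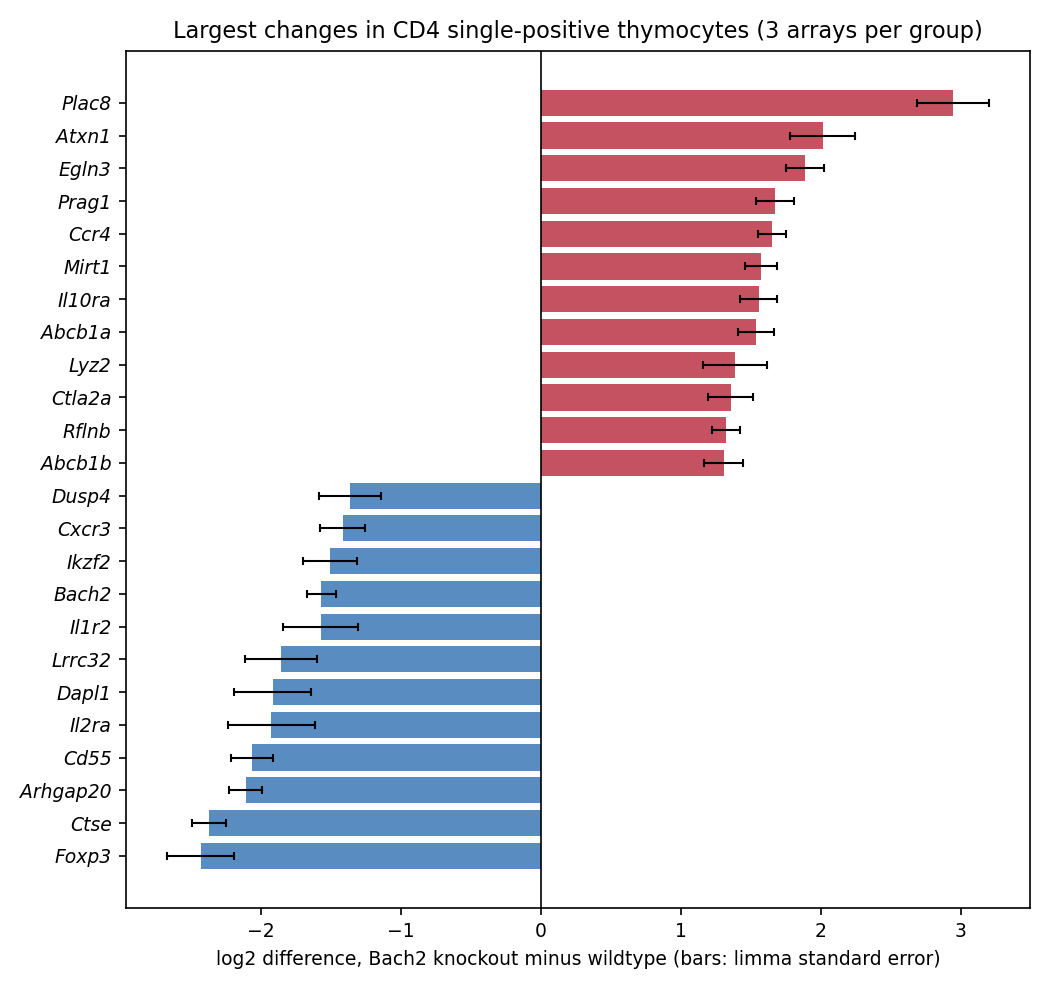
Log2 difference between knockout and wildtype thymocytes (horizontal axis) for the 12 largest rises and the 12 largest falls among the changed genes that could be named, one gene per row. Predicted genes, clone names, small RNAs and receptor segments were left out. Bars run from 0 and the whiskers are limma standard errors over 3 arrays per group; Plac8 stands highest at 2.94 and Foxp3 lowest at -2.43.

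The counts depended on the features tested, on how the spread was estimated and on single arrays. With all 35556 probe sets in the fit, 29 probe sets were higher (18 with 1 symbol, 11 with none listed) and 8 lower, 22 of the 113 calls were kept and Foxp3 had an adjusted p of 0.0743. A linear model without moderation called 1 gene higher and 0 lower (572 and 708 at an unadjusted p under 0.05), a prior that followed expression level called 78 lower, and leaving out each array in turn gave 29 to 82 higher and 18 to 66 lower, with the fewest of each without wildtype replicate 3.

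The regulatory T cell list moved furthest. Of its 22 measured members 5 fell (Foxp3, Il2ra, Lrrc32, Ikzf2 and the ectonucleotidase Nt5e) and 1 rose (Izumo1r, also known as folate receptor 4), while 15 were lower and 2 higher when adjusted over the list alone. Nt5e fell by 1.04 and Izumo1r rose by 0.92, 2 members named after their values were seen; their calls held in 2 and in 1 of the 6 fits that left out an array. In those fits Izumo1r was higher by 0.74 to 1.09. Gpr83, the other member that was higher adjusted over the list alone, differed by 0.72 without passing over all genes. The mean difference of the list was -0.70 ± 0.82 (SD between members; camera, adjusted p = 5.33e-15), with an adjusted p = 0.503 when the correlation was estimated from the data. That estimate was 0.553 against the preset 0.01, and camera's unadjusted p with it was 0.0637. By array, the list's mean was 7.16, 7.78 and 7.78 in wildtype replicates 1 to 3 and 6.86, 6.88 and 6.91 in the knockout arrays, so that wildtype replicate 1 lay nearest to the knockout.

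**Figure D2:**
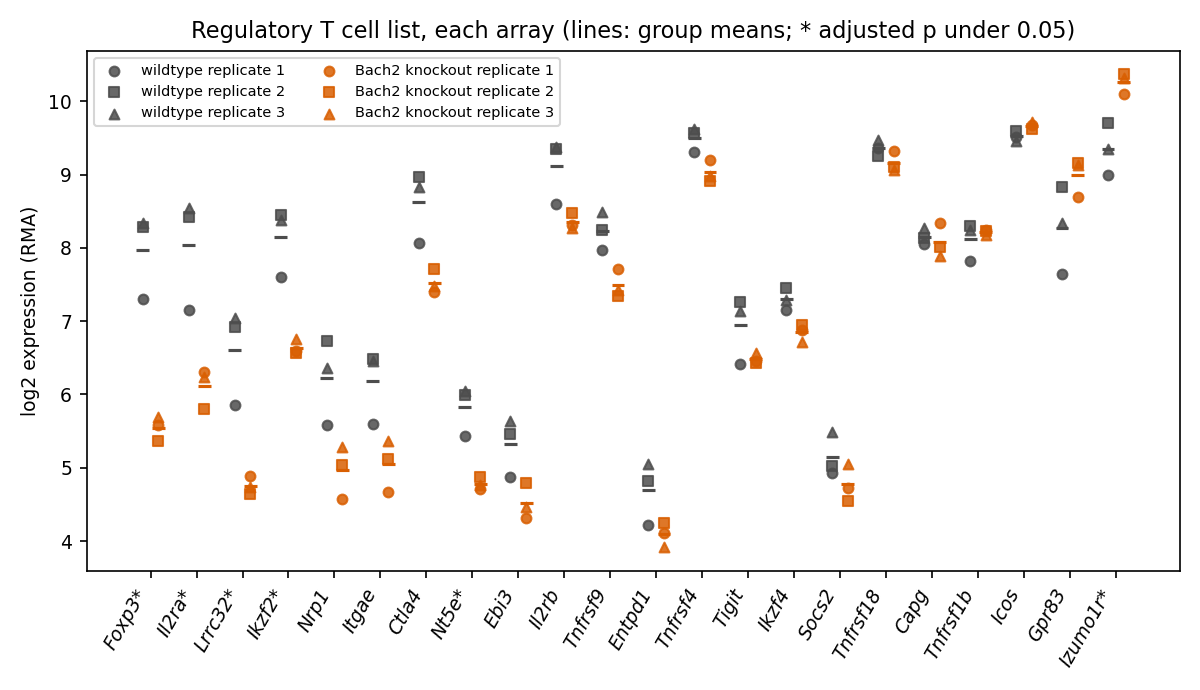
Log2 expression (vertical axis) of the 22 measured members of the regulatory T cell list on each of the 6 arrays, ordered by their difference, with short lines at the group means and a star at the 6 members with an adjusted p under 0.05. Foxp3 is at 7.30 to 8.33 in wildtype and 5.36 to 5.69 in knockout arrays, and Izumo1r is higher in the knockout.

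Among the helper programmes, 1 member of the type 1 and cytotoxic list rose and 1 fell of 22 measured. Il12rb1, a chain of the interleukin 12 receptor, rose by 0.67 and Cxcr3 fell, with 3 higher and 7 lower adjusted over the list alone. The list was lower (mean -0.25, camera adjusted p = 0.0119), with adjusted p = 0.503 at an estimated correlation. By array its mean was 5.50, 5.83 and 5.81 in wildtype replicates 1 to 3 and 5.34, 5.61 and 5.43 in the knockout, so the groups overlapped. As in the regulatory T cell list, replicate 1 was the lowest of the wildtype arrays. In the type 2 list Ccr4 rose and the other members of 16 did not pass, with 4 higher and 3 lower adjusted over the list alone. Its mean was 0.05, its median -0.09, and camera, whose direction was higher, gave adjusted p = 0.852. In the type 17 list 0 of 10 members passed over all genes by limma (3 at an unadjusted p under 0.05) and 2 were lower adjusted over the list alone (camera adjusted p = 0.179). Ccr6 differed by -1.23 (adjusted p = 0.0677) and the aryl hydrocarbon receptor Ahr by -0.52 (adjusted p = 0.0552). Cxcr3 (6.34, 7.05 and 6.78 in wildtype replicates 1 to 3) and Ccr6 (4.44, 5.42 and 5.34) were lowest in replicate 1 among the wildtype arrays, whereas Ahr and Runx3 were not. Whether the lower values in the type 1 and type 17 lists are separate from those of the regulatory T cell list was not tested. In the follicular helper list 0 of 13 passed by limma (3 unadjusted), with 1 higher and 2 lower adjusted over the list alone. Its mean was -0.04 and its median 0.04 (camera, direction lower, adjusted p = 0.978). Camera's direction turned to higher without wildtype replicate 2 (adjusted p = 0.478), where the mean was 0.03, or without knockout replicate 2 (0.99). Sh2d1a differed by 0.51 and Cd200 by -0.47. Il12rb1 lost its call in 4 of the 6 fits that left out an array (adjusted p up to 0.105). The adjusted p of the type 1 list was 0.478 without wildtype replicate 2, 0.251 without knockout replicate 1 and 0.0769 without dim genes. The type 17 list passed as lower without knockout replicate 3 (0.0406).

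Of 20 effector-memory and tissue homing genes, the calcium-binding proteins S100a6 and S100a11 rose by 0.94 ± 0.13 and 0.77 ± 0.09, and the galectin Lgals1 fell by 0.76 ± 0.11. Adjusted over the list alone, 6 were higher and 5 lower. The mean was -0.05, the median 0.02 and camera's direction higher (adjusted p = 0.897). That direction turned to lower without wildtype replicate 1 (camera adjusted p = 0.384) or without knockout replicate 2 (0.844). Of 20 naive and thymic egress genes, 3 fell (Cd55, Dapl1 and Igfbp4, a binding protein of insulin-like growth factors that fell by 0.96 ± 0.14) and Slamf6 rose by 0.62 ± 0.11, with 4 lower and 2 higher adjusted over the list alone. This list was lower (mean -0.26, median -0.07, camera adjusted p = 0.0109), with adjusted p = 0.746 at an estimated correlation. Its mean leaned on the 3 falls, with Cd55 at -2.07 and Dapl1 at -1.92. In all, 13 members lay below 0 and 7 above. Cd55 is among the tested genes nearest to Ptprc in gene order. Of the 6 fits that left out an array, Lgals1 lost its call in 4 (adjusted p up to 0.0808), Slamf6 in 5 (up to 0.226) and Dapl1 in 1 (0.0547). For the naive and egress list the adjusted p was 0.478 without wildtype replicate 2 and 0.111 without knockout replicate 1.

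The double-positive and immature thymocyte list was higher in the knockout (mean 0.30 over 16 members, camera adjusted p = 0.000506), with adjusted p = 0.503 at an estimated correlation. By limma 0 members passed over all genes and 9 had an unadjusted p under 0.05, while 5 were higher and 2 lower adjusted over the list alone. Chst2 differed by 0.53 (adjusted p = 0.0629) and Themis, a regulator of T cell receptor signalling during selection, by 0.55 (adjusted p = 0.077). The 2 lower members, named after their values were seen, were Cd24a (-0.58) and Sox4 (-0.46). The list's mean was 7.37, 7.58 and 7.48 in wildtype and 7.46, 7.76 and 8.10 in knockout replicates 1 to 3, so that the groups overlapped. Knockout replicate 3 carried much of the difference. Without it the mean was 0.14 (camera adjusted p = 0.0348), and without knockout replicate 1 it was 0.45. Cd8a was at 8.90 on knockout replicate 3 and at 7.67 to 7.90 on the other 5 arrays. Rag1, a recombinase gene of immature thymocytes named after its values were seen, was at 5.70, 6.61 and 7.09 in wildtype and 6.55, 7.92 and 8.75 in knockout arrays, which overlap.

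T cell receptor signalling and selection genes were lower as a list (mean -0.12 over 22 members, camera adjusted p = 0.0109), with adjusted p = 0.503 at an estimated correlation. The orphan nuclear receptor Nr4a3, induced by receptor signalling, fell by 0.60 ± 0.09 (adjusted p = 0.0209), and it was the 1 member past the test over all genes, with 2 lower adjusted over the list alone. Nr4a3 is among the 238 tested genes nearest to Bach2 in gene order. For Nr4a3, an allele carried along with the knockout cannot be told apart from the effect of Bach2. Its call was lost in 4 of the 6 fits that left out an array (adjusted p up to 0.12). The heme, iron and antioxidant list was higher (mean 0.08 over 17 members, camera adjusted p = 0.0486), again with adjusted p = 0.503 at an estimated correlation. By array its mean was 6.48, 6.38 and 6.35 in wildtype replicates 1 to 3 and 6.46, 6.46 and 6.54 in the knockout, so wildtype replicate 1 lay above 2 of the 3 knockout arrays. By limma 0 members passed over all genes and 2 were higher adjusted over the list alone, the same number as at an unadjusted p under 0.05. Glutathione reductase, Gsr, differed by 0.51 (adjusted p = 0.0706) and Txnrd1 by 0.37 (adjusted p = 0.217). Without wildtype replicate 2 the adjusted p was 0.478 for the receptor signalling list, whose mean was then -0.07, and 0.291 for the heme list, which also did not pass without wildtype replicate 3 (0.199), without knockout replicate 3 (0.19), after median centring of the arrays (0.0557) or without dim genes (0.174).

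In 5 further lists 0 members passed by limma, over all genes or adjusted over the list alone, and the lists did not pass by camera with all 6 arrays. Their mean differences were -0.06 for the AP-1 and MAF family (18 members, adjusted p = 0.345), -0.10 for cell cycle (24 members, adjusted p = 0.112), -0.06 for interferon response (19 members, adjusted p = 0.311), -0.06 for dissociation stress (16 members, adjusted p = 0.259) and -0.04 for apoptosis regulators (14 members, adjusted p = 0.601). At an unadjusted p under 0.05 there were 3 members in the AP-1 and MAF list, 3 in the cell cycle list, 4 in the interferon list and 0 in the last 2 lists. By camera the cell cycle list passed as lower without wildtype replicate 1 (adjusted p = 0.00901), wildtype replicate 3 (0.00341) or knockout replicate 3 (0.0061). The interferon list passed without wildtype replicate 1 (0.0123) or knockout replicate 3 (0.0061) and the dissociation stress list without knockout replicate 3 (0.0275). Without wildtype replicate 2 camera's direction turned to higher for the cell cycle list (adjusted p = 0.478) and for the interferon list (0.828). The cell cycle list's mean was 6.55 on that array and 6.12 to 6.34 on the other 5. The members with the smallest p were Fosl2 (-0.25) and Batf (-0.27), Aurkb (-0.28) and Top2a (-0.44), Oas3 (0.38) and Rsad2 (0.36), Dusp1 (-0.17) and Ier2 (-0.11), and Pmaip1 (-0.20) and Bid (-0.13).

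Of the markers of other cells that the sort could hold, the macrophage and the CD8 T cell lists passed. The macrophage and monocyte list was higher in the knockout (mean 0.28 over 11 members, camera adjusted p = 0.00225), with adjusted p = 0.503 at an estimated correlation. Lyz2 rose and the other members did not pass over all genes, while 4 were higher and 1 lower adjusted over the list alone. Lyz2 lost its call in 4 of the 6 fits that left out an array. The list's mean was 5.488, 5.302 and 5.099 in knockout and 5.090, 4.904 and 5.048 in wildtype arrays. Without knockout replicate 1 its mean difference was 0.19. The CD8 T cell list was lower (mean -0.29 over 7 members, camera adjusted p = 0.00225), with adjusted p = 0.5 at an estimated correlation. Another list also holds 5 of its members. Its estimated correlation was -0.069, under the preset 0.01, yet camera's unadjusted p rose from 0.00039 to 0.022. The correlation itself is therefore not what removed this call. Something else in that setting of camera raised its p, and may have raised the p of the other lists as well. By limma 0 members passed over all genes (4 at an unadjusted p under 0.05) and 4 were lower adjusted over the list alone. Eomes differed by -0.70 and Runx3 by -0.55, whereas Cd8a differed by 0.37. Without wildtype replicate 2 neither list passed, with an adjusted p of 0.168 for the macrophage and 0.0773 for the CD8 T cell list.

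The remaining lists of other cells did not pass by camera with all 6 arrays and held 0 members past the test by limma over all genes. Natural killer T cell genes had a mean difference of -0.16 (8 members, adjusted p = 0.179; 2 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone), and passed as lower without wildtype replicate 3 (0.0303), with Il2rb at -0.76 and Cd160 at -0.44. Natural killer and innate lymphoid genes had a mean of 0.01 (7 members, adjusted p = 0.978; 2 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone), with Fcer1g at 0.41 and Klrk1 at -0.29. B cell genes (mean 0.03, 10 members, adjusted p = 0.847), dendritic cell genes (mean 0.03, 11 members, adjusted p = 0.601), neutrophil genes (mean 0.15, 10 members, adjusted p = 0.4) and genes of thymic epithelium and stroma (mean 0.02, 11 members, adjusted p = 0.897) had 0 members past the test adjusted over the list alone, and 1, 0, 2 and 0 members at an unadjusted p under 0.05. Their members with the smallest p were Cr2 (-0.27) and Cd79a (0.30), Itgax (0.31) and Clec9a (0.12), S100a9 (0.78) and S100a8 (0.97), and Krt8 (0.25) and Epcam (-0.11). With 4 measured members each, the gamma-delta T cell list (mean -0.12) and the erythroid list (mean -0.03) were not tested. Sox13 differed by -0.27, Cd163l1 by -0.18, Alas2 by -0.20 and Epb42 by 0.08.

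**Figure D3:**
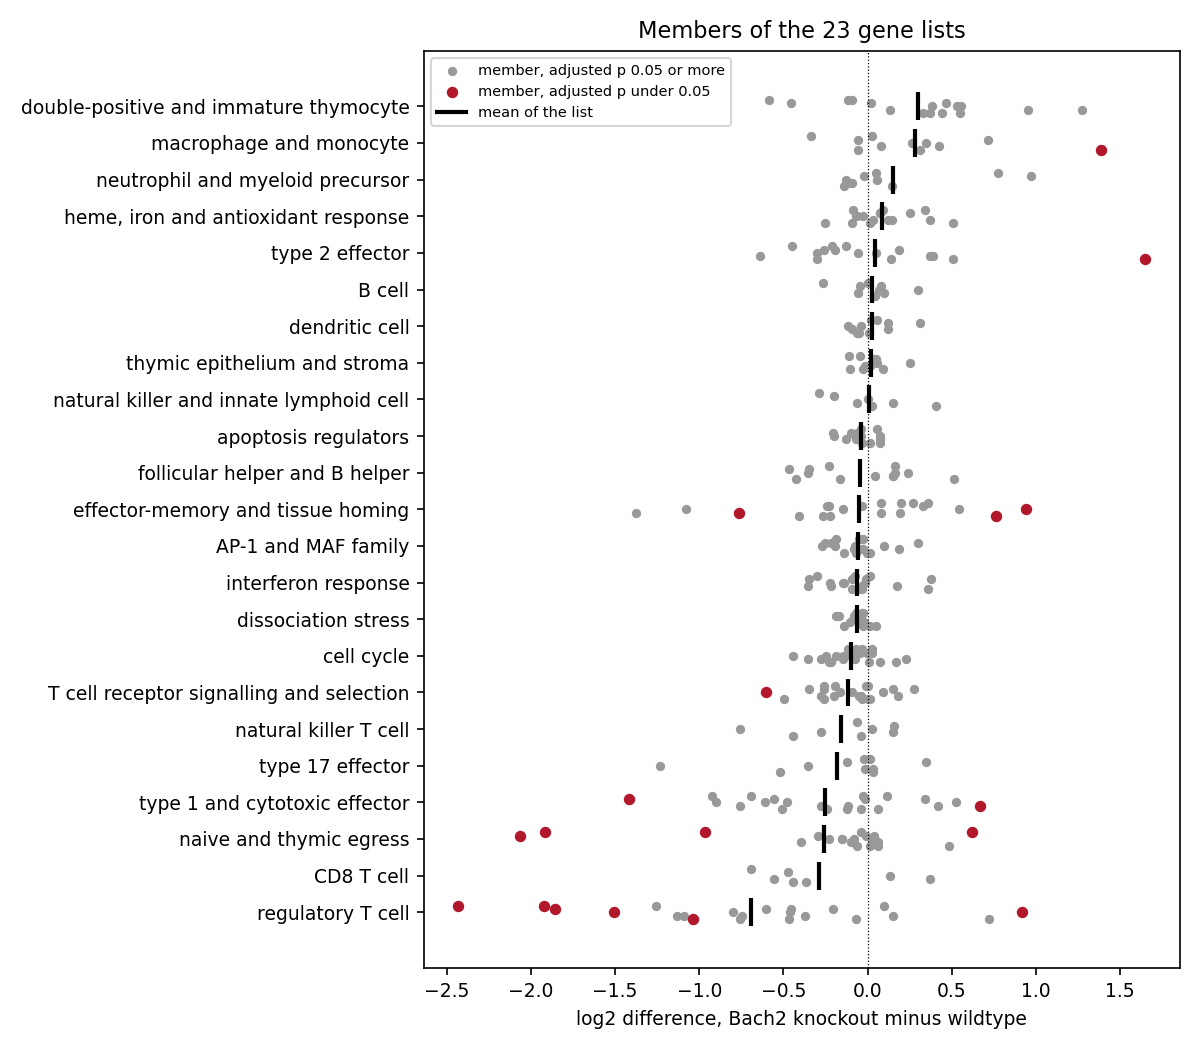
Log2 difference between knockout and wildtype thymocytes (horizontal axis) for each measured member of the 23 tested gene lists, one list per row ordered by mean. Points are genes, red where the adjusted p was under 0.05, and black bars are list means, from -0.70 for the regulatory T cell list to 0.30 for the double-positive list.

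In all, 8 of the 23 lists passed by camera at the preset correlation. Camera asks whether a list moves relative to the other genes. Fry asks whether the members of a list change at all, so counts from camera and fry answer different questions. With an estimated correlation 0 lists passed by camera (1 at an unadjusted p under 0.05), by fry's test for movement in one direction 0 passed (3 unadjusted), by fry's test for change in either direction 14 passed, and without wildtype replicate 2 camera called 2, the regulatory T cell and the double-positive lists. The adjusted p of 0.503 at an estimated correlation is a tie made by the adjustment and does not rank the lists that share it. Camera's unadjusted p there was 0.0637 for the regulatory T cell, 0.1495 for the heme and 0.1496 for the macrophage list. It was 0.1551 for the double-positive, 0.178 for the receptor signalling and 0.1969 for the type 1 list.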

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

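The probe sets without a listed gene symbol took no part in the comparisons above. In a limma fit over all 35556 probe sets, 11 of these 12146 passed adjusted p under 0.05 and all 11 were higher in the knockout; 802 had an unadjusted p under 0.05. The 11 held only 4 distinct sets of values, since 7 probe sets had identical values on every array and 2 others shared theirs. The 7 were at 6.70 ± 0.22 in wildtype and 8.65 ± 0.18 in knockout cells (SD, n = 3 each), a log2 difference of 1.96, and the 2 were at 6.62 ± 0.24 and 8.62 ± 0.18, a difference of 2.00. Probe set 10503833 differed by 0.93, from 11.19 ± 0.13 to 12.12 ± 0.07 (adjusted p = 0.0483), and probe set 10343822 differed by 1.496, from 2.91 ± 0.07 to 4.41 ± 0.29 (adjusted p = 0.0416). Both means of probe set 10343822 lay under the threshold of 4.93 for dim genes, so its values may lie at background. Which transcripts these probe sets measure was not analysed here.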

How the results depend on the processing

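Leaving out genes next to Ptprc and Bach2 was chosen after seeing the data; the other alternatives were planned. With 6 arrays most counts leaned on the moderated variance: without moderation 1 gene was higher and 0 lower, and Bach2 kept its difference of -1.57 at an adjusted p of 0.0955 (1.09e-05 to 0.0955 over its alternatives). With all 35556 probe sets 29 probe sets were higher (11 of them without a listed symbol) and 8 lower, and 22 of the 113 calls were kept; more tests and a prior of 2.45 degrees of freedom in place of 6.02 changed together. A trended prior called 78 lower, and a minimum of 2-fold left 23 higher and 18 lower. Leaving out each array in turn gave 29 to 82 higher, 18 to 66 lower and 2 to 11 gene lists; 41 of the 113 calls (26 higher, 15 lower) were kept in each of these 6 fits, 47 without wildtype replicate 3 and 91 without wildtype replicate 2. Bach2 stayed past the threshold in all 6, between -1.65 and -1.49. Of the lists, 0 passed with an estimated correlation, 2 with ranks (regulatory T cell and double-positive), 0 by fry for one direction and 14 by fry for either. Fry does not set a list against the other genes, so its counts are not directly comparable with camera's. Ptprc, never past the threshold, ran from -0.0093 without wildtype replicate 1 to 0.0542 without wildtype replicate 2. No changed gene turned its sign under any of these fits. Median centring (71 higher, 50 lower), a second quantile normalization (68 and 45), the dim filter (80 and 55), array weights (95 and 64), averaged probe sets (70 and 44) and a robust prior (70 and 42) stayed within 1.5 times. Without the 150 genes on either side of Ptprc and Bach2, 70 were higher and 37 lower. Whether a knockout and a wildtype sample shared a chimera is not clear from the labels, which name separate mice, and the replicate numbers were not taken to pair them: deviations from the group means correlated at 0.213, 0.113 and -0.065 for the numbers 1 to 3, and not every array correlated best with its own number. With the replicate block 79 genes were higher and 55 lower, 96 of the 113 calls were kept, Bach2 differed by -1.57 (adjusted p = 0.000799) and 7 lists passed, without the heme list (0.0728). Except where a setting tests fewer samples or genes, or the prior is named, the cause was not tested. Detection against background was not analysed here, so dim genes such as Clec9a may lie at background; without the genes below 4.93, 103 of the 103 calls left were kept.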

Other observations

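All tests of explanations below were chosen after the values they bear on had been seen, except the splits of the 6 arrays. Genes in this paragraph were chosen after their values were seen, and each but S100a4 was called by limma over all genes. Besides S100a6 and S100a11, S100a2 of the same family was higher in the knockout by 0.85, and S100a4 differed by -1.37 without passing (adjusted p = 0.058). The ubiquitin ligases Rnf19a and Rnf19b were higher by 0.67 and 0.69, and the tumour necrosis factor receptors Tnfrsf26 and Tnfrsf23 by 0.95 and 0.67. Axin2, a target and feedback inhibitor of Wnt signalling, was higher by 0.92 ± 0.09 (limma standard error; adjusted p = 0.00148). The oxysterol receptor Gpr183 was higher by 0.81, the inhibitory receptor Cd200r1 by 1.08, the urokinase receptor Plaur by 0.93 and the receptor-associated adaptor Trat1 by 0.81. Calls of Axin2, Trat1 and Tnfrsf26 held without each array in turn; those of Gpr183, Cd200r1 and Plaur were lost without wildtype replicate 3. S100a2, Rnf19a and Tnfrsf23 held in 3, 3 and 4 of the 6 fits that left out an array, and Rnf19b in 0.

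Wildtype arrays differed more among themselves than knockout arrays. Over all 35556 probe sets, the SD of pairwise differences was 0.348 to 0.449 within wildtype and 0.314 to 0.329 within knockout. Between genotypes it was 0.332 to 0.413. Wildtype replicate 2 had the lowest array weight, 0.399. The genes Kcnma1 and Penk were named after their values were seen. The potassium channel gene Kcnma1 was at 8.13 on that array and at 3.99 and 5.38 on the other wildtype arrays. The enkephalin precursor Penk was at 6.50, 8.96 and 8.12 in wildtype and at 5.58, 5.88 and 5.37 in knockout arrays, a difference of -2.25 that did not pass (adjusted p = 0.0923).

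Of the 10 ways to split the 6 arrays into 3 and 3, the genotypes gave 113 changed genes and the highest of the other splits gave 0, so 1 of 10 gave as many. For the gene lists 2 of 10 splits gave as many as the 8 past the threshold, the other being wildtype replicate 1 with knockout replicates 1 and 2 against the rest, with 9. With 10 splits the share cannot come under 1 of 10, so it cannot reach 0.05. Every other split holds both genotypes in each of its groups. A genotype difference then widens the spread within groups, so 0 changed genes in those splits do not measure what chance gives.

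The regulatory T cell list was lower in knockout thymocytes by a mean of -0.695. It did not pass by camera at an estimated correlation (adjusted p = 0.503) or by fry for one direction (adjusted p = 0.31). Scaling between arrays is argued against, since 0% of 10000 random lists matched on mean level were as low and the lowest was at -0.247. A smaller share of regulatory T cells, which the CD4 gate would keep, is a candidate explanation. Members that were higher in wildtype replicates 2 and 3 than in replicate 1 tended to fall most (Pearson's r = -0.612, Spearman's rho = -0.709, across 22 genes, which are not independent replicates). A correlation as low came up in 4.29% of the random lists, which is close to the bound of 5% set for it. That split of the wildtype arrays follows the list's own means. Members that fall together within cells could give the same correlation, so it cannot decide between the 2. Izumo1r (8.99, 9.71 and 9.35 in wildtype replicates 1 to 3) and Gpr83 (7.65, 8.83 and 8.34) shared the wildtype pattern but were higher in the knockout. Izumo1r went against the list and rose by 0.915. It stayed higher by 0.737 to 1.093 whichever array was left out, with every knockout array above every wildtype array. Its call held in 1 of those 6 fits, and Gpr83 differed by 0.72 without passing. Izumo1r is 1 member picked after its rise was seen, and which cells its signal came from was not tested. It therefore cannot decide whether a smaller share is the whole cause for the members that fell. A change of expression within regulatory T cells of the knockout stays open and was not tested.

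Ptprc lies among genes that a Ly5.1 congenic stretch may carry along, and 4 of its 300 nearest genes in gene order (Cd55, Ctse, Ptprv and Rgs16) changed, against 108 of 19554 elsewhere (Fisher's exact test, two-sided, p = 0.09; odds ratio 2.43, 95% interval 0.647 to 6.48). All 4 were lower in the knockout, against 38 lower genes elsewhere (p = 0.00364 by the same exact test; odds ratio 6.94, 95% interval 1.79 to 19.4), a direction picked after it was seen, whereas alleles carried along with Ly5.1 can act either way; since Ly5.1 and genotype go together, they cannot be told apart from the effect of Bach2 for these 4 genes. Probes that bind Ly5.1 transcripts less well would make the neighbours higher in the knockout, and the highest of the 4 was at -0.799. Of the 238 genes next to Bach2, 1 changed (Nr4a3; Fisher's exact p = 1).

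Changed genes tended to be neighbours in gene order: 8 same-direction pairs lay next to each other or with 1 gene between, against a mean of 0.77 in 10000 random sets matched on mean level (permutation p = 1e-04, the smallest these sets can give). Labelled cDNA of one gene binding probes of its paralog may account for the 3 pairs with related names (Abcb1a with Abcb1b, Ctla2a with Ctla2b, Tnfrsf26 with Tnfrsf23). It is argued against as the whole cause by the 5 pairs with unrelated names, among them Rundc3b with Abcb1a and with Abcb1b, and Slc39a4 with Tonsl, against a mean of 0.75 (permutation p = 0.001). These 5 pairs form 4 loci, since 2 share Rundc3b and rest on Abcb1a and Abcb1b, whose probes may not tell them apart (mean of 0.75 loci in random sets, permutation p = 0.0057), and in 2 of the 4 a pair kept both calls without each array in turn. Shared regulation of neighbours and transcripts that run from one gene into the next were not tested.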
